A study of Mus musculus with 6 samples.

How the data were processed

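Poly(A)-selected RNA was sequenced from gastrocnemius muscle of 6 mice, 3 with floxed Usp21 alleles (control) and 3 with the same alleles and Ckmm-Cre (knockout). Per the labels' protocols, tissue was kept in an RNA-stabilising solution, total RNA was extracted with Trizol, and each sample had its own library made with a kit that preserves the strand. The labels give strain, age, tissue, genotype and replicate number, with the controls' genotype entered as Litter, and do not say which animals share a litter, so p-values measure the spread between these samples. All 6 libraries had reads from Y-linked genes and at most 8 counts of Xist. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 35.1 or more within groups), so each was counted as a sample.

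The deposited table held 24532 genes with Entrez identifiers, symbols and RefSeq transcripts. Read counts per gene are whole numbers and, per the file headers, were deposited unnormalized. FPKM values, which scale fragments to gene length and library size, and TPM values, which scale them to the sum over transcripts, were also computed by the authors per the file headers. Per the submitters' processing notes, bcl2fastq 2.20.0, FastQC 0.11.7, Bowtie2 2.3.4.1 and StringTie 1.3.4d were used with the mm10 build, without roles. Which program aligned the reads, whether counts were taken read by read or derived from StringTie's coverage, and whether the strand was used are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical genes, could therefore be divided in ways the counts do not show. In 3 genes FPKM was above 1 where TPM was 0, so TPM was not used for tests. Columns of samples outside the series numbered 0. Coordinates are those of the RefSeq gene table for GRCm38.p6, the assembly that mm10 names, in which 24462 of the 24532 identifiers were found.

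The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts: filterByExpr with a minimum count of 10, TMM normalization, quasi-likelihood dispersion, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 14109 genes, and 10423 were not tested. Standard errors of log2 fold changes came from the quasi-likelihood F statistic. CPM values were scaled by the TMM factors, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 19.2%. At these depths 3 counts, the limit that a count of 0 allows, correspond to between 0.0446 and 0.0617 CPM; such floors cover counting error only, since the labels name no molecular identifiers.

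Simulated counts were drawn from the means, dispersions and library sizes of the knockout and control libraries, with 200 changed genes chosen among those above a mean of 1 CPM. The test on 13953 genes called 19.4% of genes changed by 1.5-fold, 71.6% of those changed by 2-fold and 95.5% of those changed by 4-fold. All these calls had the right direction, and 8 unchanged genes (6.1% of all calls) were called. No deviation shared by many genes of a library was simulated, so these shares may be too high for the data. In the data, Ppargc1a (5.44-fold, edgeR adjusted p = 0.241) and Nr4a3 (19.2-fold, edgeR adjusted p = 0.300) did not pass.

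Before the data were examined, 29 gene lists were fixed, 28 for testing and 1 of sex-linked genes as a check of the samples. The list of protein genes of the mitochondrial genome had no symbol in the table, so 27 were tested, with limma 3.58.1's camera at a preset correlation of 0.01 and adjustment over the lists with at least 5 tested members. Camera asks whether the mean test statistic of a list's genes differs from that of all other genes. A few members with large changes can therefore carry a list. Counts adjusted over the list alone used the same p-values with only the list's members in the adjustment.

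Genes were named by a rule also fixed in advance. It takes Usp21, the 12 genes with the smallest p in each direction among those past the threshold whose groups did not overlap, or the 5 with the smallest p in a direction where fewer than 5 passed, and of each list the members past the threshold, at most 6, or else the 2 with the smallest p. Names outside it are given as chosen after their values were seen. The values of 1 gene are not reported here.

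Alternatives fixed before the data were examined were DESeq2's size factors and upper-quartile scaling in edgeR, no filter, a filter of 1 CPM in every library of a group, DESeq2 1.42.0's Wald test, limma-voom, limma with a trend on log2 of FPKM plus 1 or plus 0.1, a replicate term, leaving out each library in turn, an adjusted p under 0.10, a fold change of at least 1.5, and, for lists, camera with an estimated correlation and fry. DESeq2 gave 554 genes no adjusted p, and these stayed out of its counts.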

Results

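The data were gene counts from poly(A)-selected, strand-preserving RNA libraries of whole gastrocnemius, the large calf muscle, taken from 12-week-old C57BL/6 mice. Usp21 encodes a ubiquitin-specific protease, an enzyme that removes ubiquitin from proteins. In 3 knockout mice the floxed Usp21 alleles were exposed to Ckmm-Cre, a Cre recombinase driven by the muscle creatine kinase promoter, and 3 control mice carried the floxed alleles alone. Total counts were 48658436, 60785548 and 67332846 in control libraries 1 to 3 and 65425324, 53906493 and 55143555 in knockout libraries 1 to 3. Between 15609 and 15953 genes had at least 1 count, and the 10 most abundant genes took 22.1% to 27.3% of each library. The series asks how loss of Usp21 alters the muscle transcriptome, so the single comparison was knockout against control, with log2 fold changes given as knockout minus control.

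Usp21 (Entrez 30941; mm10, chromosome 1, 171281949 to 171287961) was lower in every knockout library than in every control library. Its level was 19.2 ± 0.0762 CPM (counts scaled to library size; SD, n = 3) in control muscle and 7.91 ± 1.02 CPM (SD, n = 3) in knockout muscle, or 41.1% of the control mean. The individual values were 19.3, 19.3 and 19.2 CPM in controls and 9.08, 7.19 and 7.47 CPM in knockouts. The log2 fold change was -1.28 (SE 0.11; edgeR adjusted p = 0.0355), and an exact permutation test of log2 CPM gave a two-sided p of 0.1, the smallest that 3 against 3 libraries allow. Counts covered the whole gene, and the labels do not give the deleted exons. The adjusted p ranged from 0.0185 to 0.186 when single libraries were left out; the call was lost without control 1 (0.186), control 2 (0.129), control 3 (0.0944) or knockout 2 (0.154).

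Besides Usp21, 7 genes passed the threshold. The gene with the smallest p was Ucp3, a mitochondrial carrier abundant in skeletal muscle, which rose from 116 ± 17.3 to 560 ± 41.8 CPM (SD, n = 3 each; log2 fold change 2.27, SE 0.13, edgeR adjusted p = 0.00319). Pdk4, the kinase that inhibits pyruvate dehydrogenase and so restrains glucose oxidation, rose from 416 ± 111 to 1747 ± 209 CPM (2.07, SE 0.20, adjusted p = 0.0355). Cpt1a, the liver-type isoform of the enzyme that commits long-chain fatty acids to mitochondrial oxidation, rose from 11.9 ± 0.919 to 21.0 ± 0.178 CPM (0.82, SE 0.089, adjusted p = 0.0421). The more abundant muscle-type isoform Cpt1b, chosen after its values were seen, stood at 368 ± 48.8 CPM in controls and 377 ± 37.2 CPM in knockouts (0.037, SE 0.12, adjusted p = 0.934), a difference smaller than its spread. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 37.5 ± 3.07 to 193 ± 56.2 CPM (2.36, SE 0.22, adjusted p = 0.0355). Map3k6, a stress-responsive kinase, rose from 24.6 ± 2.22 to 47.6 ± 3.41 CPM (0.95, SE 0.097, adjusted p = 0.0421).

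The genes that fell, apart from Usp21, were Sec14l5 and Insig1. Sec14l5, a member of the SEC14-like lipid-binding family, fell from 16.4 ± 0.991 to 8.41 ± 0.672 CPM (SD, n = 3 each; log2 fold change -0.96, SE 0.10, edgeR adjusted p = 0.0421). Insig1, an endoplasmic reticulum protein that restrains sterol synthesis and is itself a target of sterol regulatory element-binding proteins, fell from 17.4 ± 0.173 to 10.1 ± 0.459 CPM (-0.78, SE 0.083, adjusted p = 0.0421). Fewer than 5 genes passed in this direction, so the next in order of p are given as well, although neither passed. Cxxc5 was at 16.4 CPM in controls and 8.90 CPM in knockouts (-0.88, adjusted p = 0.121). Bhlhe40, a transcriptional repressor linked to the circadian clock, was at 221 and 89.6 CPM (-1.30, adjusted p = 0.121).

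Ucp3 lies on chromosome 7 (Entrez 22229; 100472991 to 100486432), Pdk4 on chromosome 6 (27273; 5483351 to 5496278), Cpt1a on chromosome 19 (12894; 3322326 to 3385735), Lars2 on chromosome 9 (102436; 123366927 to 123462675) and Map3k6 on chromosome 4 (53608; 133237979 to 133252929). Sec14l5 lies on chromosome 16 (665119; 5146906 to 5187271) and Insig1 on chromosome 5 (231070; 28071412 to 28078662).

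**Figure D1:**
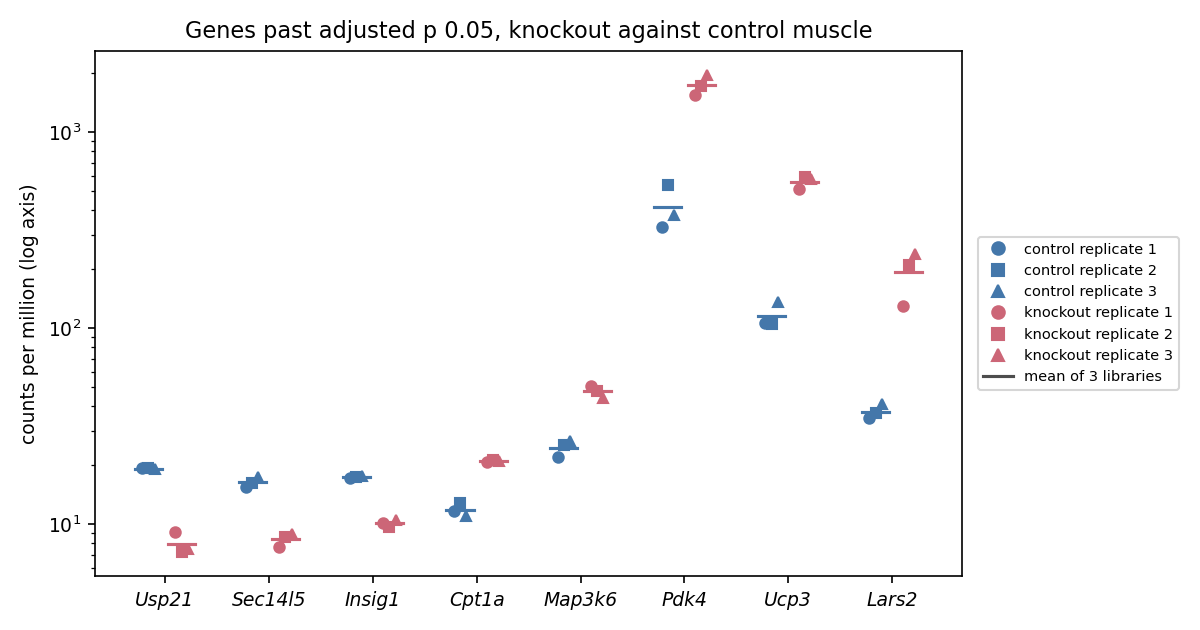
CPM (log axis) of the 8 genes past adjusted p 0.05 in each of the 6 libraries, with blue for control, red for knockout and a line at the mean of the 3 libraries. The groups do not overlap for any of the 8, with Ucp3 at 116 CPM in controls and 560 CPM in knockouts on average.

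Over all 14109 genes tested, 5 were higher and 3 lower in knockout muscle at an edgeR adjusted p under 0.05. At an unadjusted p under 0.05, 925 were higher and 715 lower. The groups did not overlap in log2 CPM for 17.3% of genes, against 4.2% to 19.2% in the other 9 splits of the libraries into 3 and 3. The highest of these, with controls 1 and 2 and knockout 3 against the rest, also had 1830 genes at an unadjusted p under 0.05, more than the 1640 of the real split. The counts rested on the choice of libraries. They were 2 higher and 0 lower without control 1 and likewise without control 2, 1 and 0 without control 3, 2 and 1 without knockout 1, 1 and 0 without knockout 2, and 120 and 21 without knockout 3. Of the 8 genes, Ucp3 was the only one to stay past the threshold in each of these fits, and all 8 did so without knockout 3. DESeq2's Wald test on the same counts called 210 genes higher and 80 lower, and limma-voom called 4 and 1.

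Genes of fatty acid uptake and oxidation stood higher as a list in knockout muscle. Of 32 members measured, 29 had a positive and 3 a negative log2 fold change, with a median of 0.14 (camera adjusted p = 1.66e-11; adjusted p = 0.634 with an estimated correlation). Without control 3 the median turned to -0.016, without knockout 3 it was 0.067 and without knockout 2 it was 0.26, with the test upward in each. Over all genes, 2 members rose (Ucp3 and Pdk4) and 30 were not called. Adjusted over the list alone, 6 rose. Among these, and named after their values were seen, were Angptl4, an inhibitor of lipoprotein lipase (1.88 and 14.3 CPM in controls and knockouts; log2 fold change 2.92, SE 0.40), and the acyl-CoA thioesterases Acot1 (1.26, SE 0.26) and Acot2 (1.18, SE 0.17). Acot1 and Acot2 are close paralogs, so the division of reads between them is uncertain.

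The list of thermogenesis and calcium cycling also stood higher, with 15 of 19 members positive and a median of 0.081 (camera adjusted p = 2.69e-05; adjusted p = 0.192 with an estimated correlation). Among its calcium-cycling members, Atp2a1 was at 0.039, Ryr1 at 0.0069, Cacna1s at 0.044 and Sln at 0.054. Atp2a2 was at 0.37 (SE 0.53) and Pln at -0.69. All of these but Pln were named after their values were seen. Without single libraries the list's median ran from 0.068 (knockout 1) to 0.21 (control 1), and with FPKM plus 1 it was 0.020. Its called member was Ucp3, shared with the fatty acid list; adjusted over the list alone, 3 rose: Ucp3, Ucp2 (19.2 and 36.9 CPM; log2 fold change 0.94, SE 0.13; named after its values were seen) and Ppargc1a. Ppargc1a encodes a coactivator that drives mitochondrial gene programmes and averaged 49.3 ± 13.2 CPM in controls and 268 ± 169 CPM in knockouts (SD, n = 3 each; 2.44, SE 0.52, edgeR adjusted p = 0.241).

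Lipid synthesis moved the other way. Of 35 measured genes of fatty acid, triglyceride and sterol synthesis, 28 had a negative and 7 a positive log2 fold change, with a median of -0.083 (camera adjusted p = 0.00332; adjusted p = 0.218 with an estimated correlation). Without single libraries it ran from -0.14 (knockout 3) to -0.058 (control 2). Insig1 was the 1 member called over all genes. Adjusted over the list alone, 2 fell, the second being Srebf1, the transcription factor that drives lipogenic genes, at 112 ± 24.5 CPM (SD, n = 3) in controls and between 41.6 and 56.8 CPM in the 3 knockouts (-1.17, SE 0.18, edgeR adjusted p = 0.133; chosen after its values were seen).

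The core machinery of energy metabolism did not pass as lists. Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.025 over 79 genes (camera adjusted p = 0.608), with Ndufa12 at 0.21 and Uqcrb at 0.18. The tricarboxylic acid cycle had a median of 0.11 over 23 genes (adjusted p = 0.104), with Dlst at 0.24 and Idh3a at 0.21. Glycolysis and glycogen genes had a median of 0.12 over 33 genes (adjusted p = 0.104). Adjusted over that list alone, Pfkfb3, which makes an activator of phosphofructokinase, fell from 209 ± 64.5 to 80.1 ± 21.5 CPM (SD, n = 3 each; -1.38, edgeR adjusted p over all genes = 0.241). Hk2, a hexokinase, was at 0.48 and did not pass. Regulators of mitochondrial biogenesis had a median of -6.4e-05 over 28 genes (mean 0.10, adjusted p = 0.401), and adjusted over the list alone Ppargc1a and Nrip1 (0.71) rose. The list of AMPK, insulin and glucose uptake had a median of 0.0098 over 32 genes (adjusted p = 0.985), with Irs2 at 1.00 and Camkk2 at 0.55. When single libraries were left out, the medians ran from -0.020 to 0.074 for oxidative phosphorylation, from 0.014 (control 3) to 0.15 for the tricarboxylic acid cycle and from 0.037 (control 2) to 0.21 (control 3) for glycolysis. They ran from -0.051 to 0.035 for mitochondrial biogenesis and from -0.041 to 0.018 for AMPK and insulin.

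**Figure D2:**
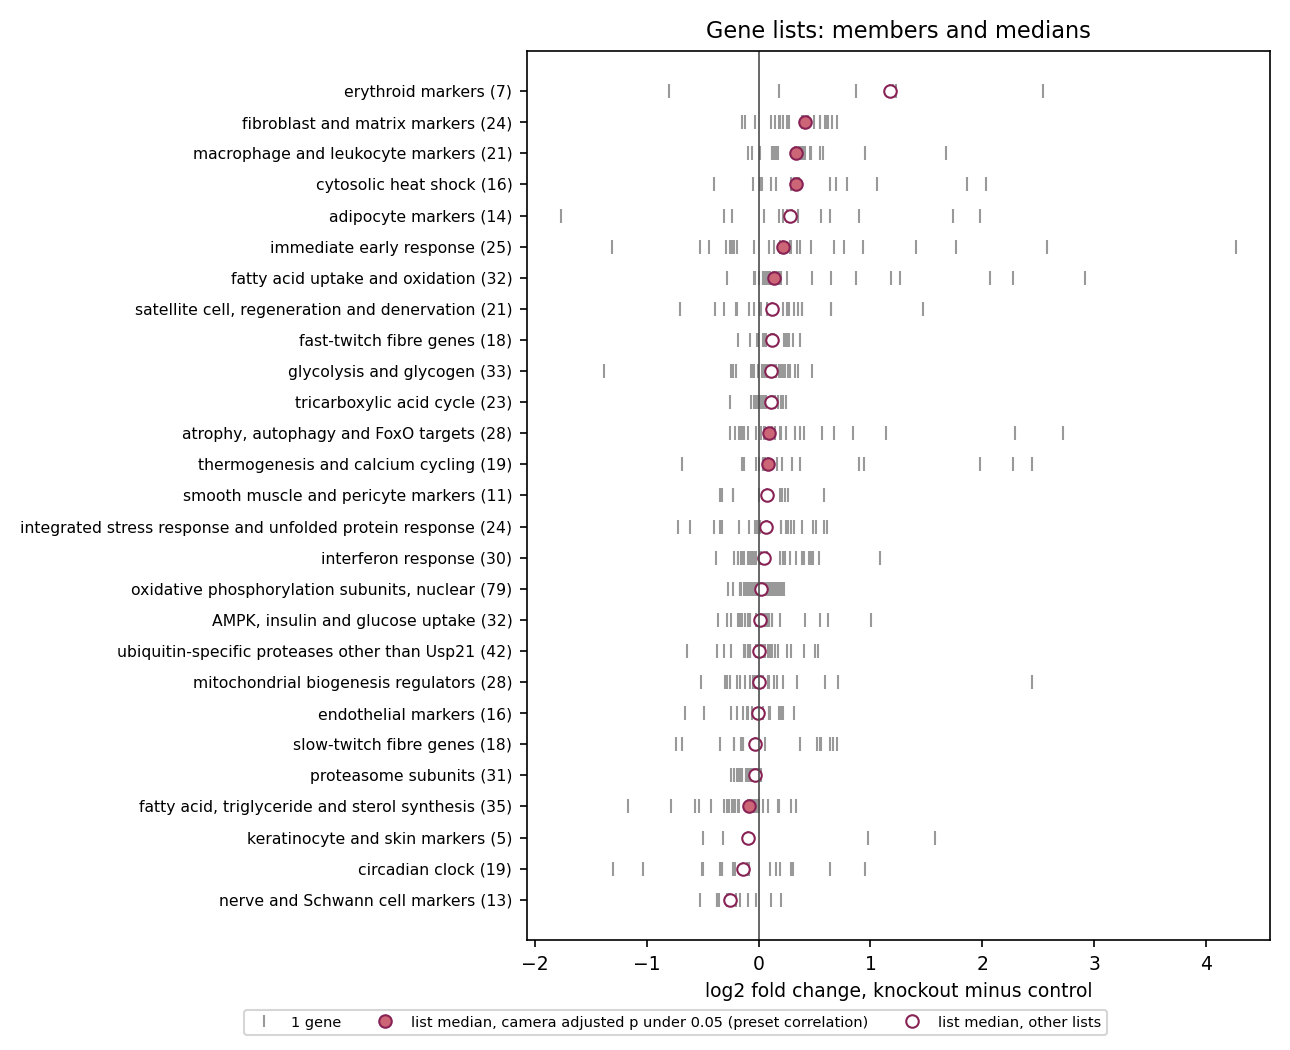
Log2 fold changes (knockout minus control, x axis) of the tested members of the 27 gene lists, 1 tick per gene, with each list's median as a circle and its number of tested genes in parentheses. Filled circles mark the 8 lists with a camera adjusted p under 0.05 at the preset correlation, of which 7 lie above 0 and lipid synthesis (-0.083) below.

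Atrophy, autophagy and FoxO target genes stood higher in knockout muscle, with 18 of 28 members positive and a median of 0.093 (camera adjusted p = 0.00664; adjusted p = 0.218 with an estimated correlation). The median ran from 0.052 (without knockout 3) to 0.14 (without knockout 1) and was 0.011 with FPKM plus 1. None was called over all genes by edgeR at an adjusted p under 0.05. Adjusted over the list alone, 5 rose. They were Foxo1 itself (65.1 and 104 CPM in controls and knockouts; log2 fold change 0.68), the muscle ubiquitin ligase Trim63 (313 and 686 CPM; 1.13), the cell cycle inhibitor Cdkn1a (0.57) and the metal-binding Mt1 (2.29) and Mt2 (14.7 and 97.2 CPM; 2.72). The last 3 were named after their values were seen. So was Fbxo32, another muscle ubiquitin ligase of the list, which did not pass when adjusted over the list alone (0.19, SE 0.14).

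Cytosolic heat shock genes had a median of 0.33, with 14 of 16 positive (camera adjusted p = 0.000987; adjusted p = 0.799 with an estimated correlation), and no member passed on its own, with Hspa8 at 0.64 and Hsph1 at 0.69. Its median was 0.19 without control 3 and 0.56 without control 2. Immediate early genes had a median of 0.22, with 16 of 25 positive (camera adjusted p = 0.0295; adjusted p = 0.799 with an estimated correlation). Adjusted over that list alone, 4 rose, namely the orphan nuclear receptors Nr4a3 (4.26) and Nr4a1 (0.93) and the transcription factors Myc (0.76) and Maff (1.77), and the phosphatase Dusp1 (-0.52) fell; Nr4a1, Maff and Dusp1 were named after their values were seen. The immediate early list was not called without control 1 (adjusted p = 0.0836), control 3 (0.963), knockout 1 (0.148) or knockout 2 (0.121), and its median ran from 0.11 (without control 1) to 0.54 (without control 2).

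Some of these genes were uneven among the knockout mice, whereas Dusp1 (69.5, 80.6 and 72.0 CPM in knockouts 1 to 3) was not. Unevenness was not tested over the lists. Nr4a3 stood at 388, 302 and 14.1 CPM in knockouts 1 to 3, against 7.66 to 19.3 CPM in controls. Hspa1a stood at 74.4, 125 and 10.7 CPM against 10.4 to 33.7 CPM in controls. Its near-identical neighbour Hspa1b, with which reads may be shared, stood at 61.9, 102 and 7.41 CPM. Ppargc1a was at 422, 293 and 87.7 CPM in the knockouts and Mt1 at 151, 107 and 35.8 CPM, in both cases still above every control. Ucp3 was at 512, 592 and 575 CPM and Pdk4 at 1553, 1718 and 1968 CPM, so knockout 3 did not stand apart for these. Hspa1a and Hspa1b were chosen after their values were seen.

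**Figure D3:**
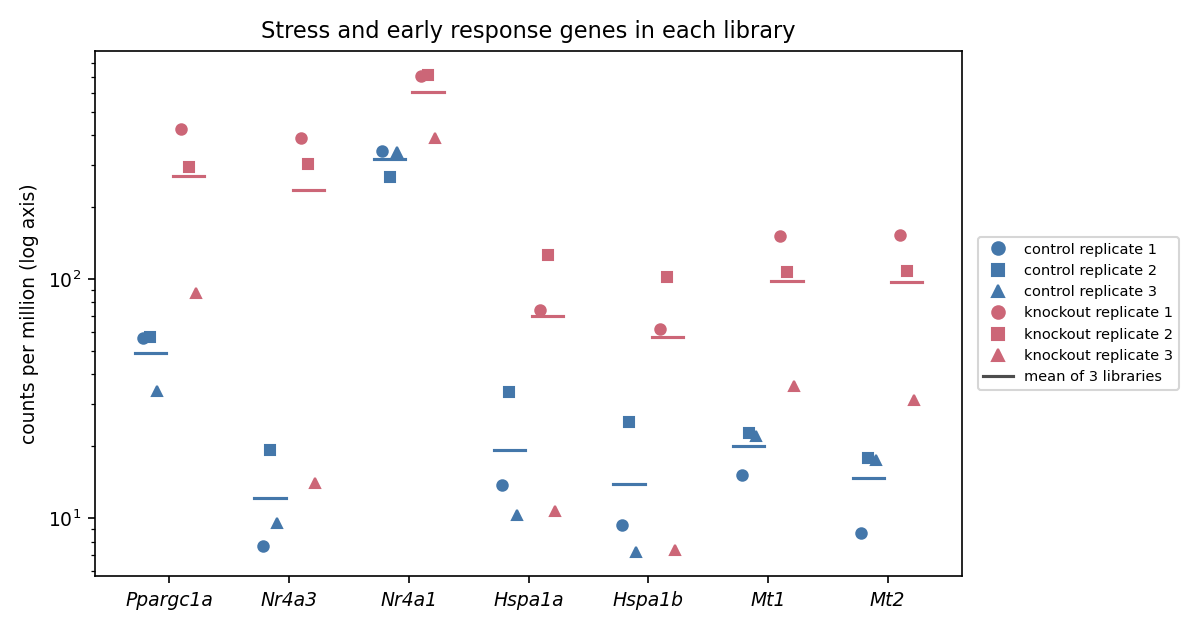
CPM (log axis) of Ppargc1a, early response, heat shock and metallothionein genes in each library, blue for control, red for knockout, with a line at the mean of 3 libraries. Knockout 3 (red triangle) lies near the controls for Nr4a3 (14.1 CPM), Hspa1a (10.7 CPM) and Hspa1b (7.41 CPM).

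The circadian clock list was not called (median -0.13 over 19 genes, -0.18 to -0.082 without single libraries, camera adjusted p = 0.0734), but some of its members differed in opposite directions. Adjusted over the list alone, Per2 (0.63) and Nfil3 (0.95), both chosen after their values were seen, rose, while Nr1d1 (242 and 119 CPM in controls and knockouts; -1.03) and Bhlhe40 (-1.30) fell. None passed by edgeR over all genes.

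Among the protein turnover and stress lists, proteasome subunits had a median of -0.035 over 31 genes, 27 of them negative (camera adjusted p = 0.104), with Psma7 at -0.22 and Psmd3 at -0.17. The other ubiquitin-specific proteases had a median of 0.0030 over 42 genes, 21 positive and 21 negative (adjusted p = 0.985), with Usp2 at 0.50 and Usp20 at -0.37. Fry's mixed test, which asks for changes in either direction, called this list (adjusted p = 0.00798). That test makes no comparison with other genes, and over all 14109 genes 1640 had an unadjusted edgeR p under 0.05. No member of this list passed when adjusted over the list alone. The integrated stress and unfolded protein response had a median of 0.071 over 24 genes (adjusted p = 0.453), with Dnajb9 at 0.39 and Trib3 at -0.72. Interferon response genes had a median of 0.050 over 30 genes (adjusted p = 0.245), with Oas2 at 0.54 and Gbp7 at 0.47. Without single libraries these medians ran from -0.11 to 0.030 for the proteasome, from -0.0090 to 0.027 for the proteases, from 0.040 to 0.18 for the stress response and from -0.0076 to 0.19 for interferon genes.

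Fibre type genes did not pass. Slow-twitch genes had a median of -0.031 and a mean of 0.076 over 18 genes (camera adjusted p = 0.453, direction up, so median and test differed in sign), with Pln at -0.69 and Fhl2 at 0.55. Their mean log2 CPM, computed after the list result was seen, was 6.26, 6.30 and 3.67 in controls 1 to 3 and 5.85, 5.39 and 6.35 in knockouts 1 to 3, so control 3 stood far below the other libraries. The direction of this list changed with the library left out. Without control 3 the median was -0.46 (adjusted p = 0.00187, direction down), and without control 1 or control 2 it was 0.19 (0.0161, up) or 0.26 (0.0381, up). Without knockouts 1 to 3 in turn it was -0.025 (0.449, up), 0.17 (0.109, up) and -0.29 (0.831, down). Fast-twitch genes had a median of 0.12 over 18 genes (adjusted p = 0.104), with Myot at 0.31 and Myoz3 at 0.26. Genes of satellite cells, regeneration and denervation had a median of 0.12 over 21 genes (adjusted p = 0.104), with Vcam1 at 0.65 and Chrnb1 at 0.38. Without single libraries the fast-twitch median ran from -0.015 (control 2) to 0.22 (control 3) and that of satellite cell genes from 0.10 to 0.18.

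Markers of other cell types moved apart from one another. Fibroblast and matrix markers stood higher, with 21 of 24 positive and a median of 0.42 (camera adjusted p = 1.43e-08; adjusted p = 0.680 with an estimated correlation). Adjusted over the list alone, Sparc rose from 205 ± 28.4 to 314 ± 27.4 CPM (SD, n = 3 each; 0.61, edgeR adjusted p over all genes = 0.237), and Col3a1, a fibrillar collagen, was at 0.62. Macrophage and leukocyte markers had a median of 0.34, with 19 of 21 positive (adjusted p = 0.00254; adjusted p = 0.799 with an estimated correlation), with Itgam at 0.95 and Fcer1g at 0.58; this call was lost without control 1 (adjusted p = 0.0865) or knockout 1 (0.148). Without single libraries the macrophage median ran from 0.17 (knockout 1) to 0.61 (control 2) and the fibroblast median from 0.32 (knockout 1) to 0.56 (control 2). Endothelial markers had a median of -0.0088 over 16 genes (adjusted p = 0.850), with Kdr at -0.65 and Ptprb at 0.21. Smooth muscle and pericyte markers had a median of 0.078 over 11 genes (adjusted p = 0.903), with Acta2 at 0.27 and Notch3 at -0.32. Their medians ran from -0.073 to 0.048 and from 0.060 to 0.10 without single libraries.

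The remaining lists did not pass either. Nerve and Schwann cell markers had a median of -0.25 over 13 genes (camera adjusted p = 0.165), with Sox10 at -0.37 and Fxyd3 at -0.52; the median was 0.13 without knockout 2, -0.043 without control 3 and -0.96 without knockout 3. Adipocyte markers had a median of 0.28 over 14 genes (adjusted p = 0.165), with Lep at -1.77 and Cidea at 1.98; the median was -0.10 without knockout 2 and 0.68 without control 3. Erythroid markers had a median of 1.18 over 7 genes (adjusted p = 0.104) and 0.038 without knockout 2; Hbb-bs stood at 559 CPM in knockout 2 and at most 142 CPM in the other libraries, and Hbb-b2, a similar globin whose reads may be shared, followed it (1.20). Keratinocyte and skin markers had a median of -0.097 and a mean of 0.33 over 5 genes (adjusted p = 0.861, direction up), with Trp63 rising when adjusted over the list alone (1.57) and Krt10 at -0.49; this median ran from -0.19 to 0.053 without single libraries.

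Of the 27 lists, 8 passed camera with the preset correlation of 0.01, 7 upward and 1 downward. With an estimated correlation 0 passed, although 3 had an unadjusted p under 0.05, and 0 passed fry, limma's rotation test for a net shift. Fry's mixed test called 6, namely fatty acid uptake and oxidation (adjusted p = 6.2e-05), thermogenesis (0.000106), atrophy and FoxO targets (0.00767), the other ubiquitin-specific proteases (0.00798), the circadian clock (0.0177) and lipid synthesis (0.0182). Of the 19 lists not called, 12 had a median that changed sign when 1 library was left out. At the preset correlation, lists not called with all libraries passed without single ones, besides the slow-twitch genes. These were the tricarboxylic acid cycle without control 1 (adjusted p = 0.0061) or knockout 2 (0.0147), satellite cell genes (0.0284) and Schwann cell markers (0.00844, down) without control 1, and proteasome subunits (0.00178, down) and the clock (0.00483, down) without control 2. Without control 3 they were fast-twitch genes (0.000436), glycolysis (0.0109), adipocyte markers (0.0174) and endothelial markers (0.0281, down). Without knockout 1 they were fast-twitch genes (0.0469), adipocyte markers (0.0384) and erythroid markers (0.000179), and without knockout 3 the integrated stress response (0.0235) and Schwann cell markers (0.000214, down).

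The libraries did not fall fully apart by genotype. The first principal component of log2 CPM held 32.1% of the variance and placed knockouts 1 and 2 at 24.7 and 44.5, while knockout 3 at -14.8 lay among the controls at -24, -19.4 and -10.9. The second held 23.9% and set control 3 (44.2) apart from the other libraries (-17.8 to 7.5).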

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

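Among the 10423 genes too low to be tested, 4 had 0 counts in all 3 control libraries and more than 3 counts, the limit that a count of 0 allows, in every knockout library. Mmp8, a collagenase of neutrophils, had 7, 6 and 6 counts in knockouts 1 to 3. Tnfsf8, a cytokine of the tumour necrosis factor family, had 6, 5 and 5. The genes known by clone names, 1700102H20Rik and 4930539E08Rik, had 10, 7 and 8 and 8, 5 and 5 counts. The lowest counts were thus 6, 5, 7 and 5. In the opposite direction 3 untested genes, Cnga2, Ifnlr1 and Rnf207, had 0 counts in every knockout library and 4 to 8 in every control library, so the excess lay on both sides. These genes were singled out after their counts were seen, and no technical explanation was tested for them. The limit of 3 counts assumes that reads were counted singly, which the sources used here do not state. How many such genes other splits of the libraries give was not counted.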

How the results depend on the processing

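All 8 genes kept their direction in each of the 15 refitted alternatives. Counts of 5 higher and 3 lower were the same with both other scalings, both other filters, the adjusted p limit of 0.10 and the fold limit of 1.5. DESeq2's Wald test gave 210 and 80, including all 8 genes, and limma-voom 4 and 1, without Cpt1a, Insig1 and Sec14l5. The FPKM fits gave 1 and 0 with either pseudocount, and Usp21, at -1.15 with 1 and -1.34 with 0.1 added, had adjusted p of 0.0657 and 0.0552. Without single libraries the counts ran from 1 to 120 higher and from 0 to 21 lower, and Usp21 from -1.40 to -1.22; these fits had 1 library fewer. Ucp3 passed in 14 of the 15 alternatives, with adjusted p up to 0.0849, Lars2, Pdk4 and Usp21 in 8, Map3k6 in 7, and Cpt1a, Insig1 and Sec14l5 in 6. List calls ranged from 7 to 12, and were 0 with an estimated correlation and 0 with fry. Of the 8 lists, 5 passed in all 15; the FoxO list was lost with limma-voom and both FPKM fits, and the immediate early list also with the stricter filter and limma-voom. The median of the fatty acid list was as low as -0.016, with its test still upward. Cpt1b, never called, turned to -0.030 with both FPKM fits, and ran from -0.064 (without control 3) to 0.12 without single libraries, with -0.037 without knockout 3. The cause of these changes was not tested. With a replicate block 0 genes were higher and 0 lower, and Usp21 stood at -1.29 (adjusted p = 0.200, range over its alternatives 1.09e-17 to 0.200). Deviations of libraries that share a number correlated at -0.008, -0.186 and -0.098, which gave no sign that the numbers pair the samples. With 3 libraries per group, pairing cannot be excluded by this check. In the simulation at this depth and number, genes changed by 1.5-fold were mostly missed.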

Other observations

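Amd1 and Amd2 encode near-identical copies of S-adenosylmethionine decarboxylase, the enzyme that feeds polyamine synthesis. Amd1 was at 1.76, 1.84 and 8.59 CPM in controls 1 to 3 and 0.199, 0.119 and 0.0730 CPM in knockouts 1 to 3 (log2 fold change -4.91, SE 0.82, edgeR adjusted p = 0.167), whereas Amd2 was at 1648 ± 491 and 1979 ± 330 CPM (SD, n = 3 each; 0.26, adjusted p = 0.677). Reads of Amd1 were a small part of those of the pair in every library, so their division between the copies is uncertain. Both genes were named after their values were seen.

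Results of the planned tests are repeated in the following paragraphs, among them camera with an estimated correlation for lists fixed in advance. The other tests there were chosen after the results were seen, except the count of called genes over splits of the libraries, which was planned.

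Lars2 rose about as much as Ucp3 in all 3 knockouts. Its annotated transcript of 3894 bases holds a stretch from base 3278 to 3349 that matched Gm15564 at 98.6% identity over 72 bases, and AA474408 at 80.1% over 196 bases from base 3163; neither gene is in the table, so reads shared with such sequences cannot be told apart from Lars2 reads. Carried-over mitochondrial ribosomal RNA, not in the table, is argued against, since it matched at most 14 bases of Lars2. Rn45s, the nuclear precursor, was named after its values were seen and had no sequence here to compare with Lars2. Its log2 fold change was 0.39 (SE 0.29) against 2.36 for Lars2. Lars2 stood at 7.87% to 8.96% of Rn45s in knockouts and 1.54% to 2.82% in controls. This argues against a rise of the whole precursor in proportion, but not against reads of a similar fragment. Over knockouts 1 to 3 Lars2 (131, 211 and 239 CPM) and Rn45s (1457, 2676 and 3002 CPM) rose together. In controls 1 to 3 they did not (34.8, 36.9 and 40.9 CPM, and 2255, 1310 and 1869 CPM). Nuclear ribosomal RNA therefore stays open. DNA of another strain around Lars2, such as a Cre line may bring, also stays open: of 62 tested genes within 5 Mb, 19.4% had an unadjusted p under 0.05, against 11.6% of other genes (two-sided Fisher's exact p = 0.0707; neighbouring genes are not independent), and 0 were called. An effect of Usp21 loss on Lars2 remains an untested hypothesis.

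Ucp3, Pdk4 and Cpt1a were higher and Insig1 lower, without a call for glycolysis as a list and with Cpt1b at 0.037. With each library's slow-twitch mean log2 CPM as a covariate all 4 genes stayed past the threshold (highest edgeR adjusted p = 0.0385). Ucp3 was at 2.34 (SE 0.082) after 2.27 (SE 0.13) and Cpt1a at 0.80 (SE 0.080) after 0.82 (SE 0.089). That mean was 0.45 (SE 0.91) higher in knockouts (5.85, 5.39 and 6.35, against 6.26, 6.30 and 3.67 in controls). It varied mainly through control 3, so the covariate alone decides little. Controls 1 and 2 exceeded knockouts 1 and 2 in this mean, yet Ucp3 was at 107 and 105 CPM against 512 and 592 CPM. These values argue against a larger share of slow-twitch fibres. Other oxidative fibres were followed only through Myh2, a fast oxidative fibre gene held in the slow-twitch list. Named after its values were seen, Myh2 was at -0.034 (SE 0.50). That spread is too wide to decide, so the share of these fibres stays open. Time of day at sampling may contribute and stays open. The clock genes' median absolute log2 fold change was 0.31, at percentile 100 of 10000 random lists of like expression (median 0.11). It was also above the 0.048 to 0.17 of the other 9 splits of the libraries. The random lists were matched on expression alone, not on spread or on genes moving together. As a directional list the clock did not pass camera (adjusted p = 0.0734 at the preset, 0.479 with an estimated correlation). Food intake before sampling also stays open, because the FoxO list passed with the preset but not with an estimated correlation (adjusted p = 0.218). Time of day and food intake were judged by unlike tests, so they cannot be ranked. The labels used here give neither hour nor feeding, so neither can be told apart from genotype. Loss of Usp21 may itself act on the clock or on fuel use, which was not tested.

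Fibroblast and matrix markers stood higher in knockouts (adjusted p = 0.680 with an estimated correlation), as did macrophage and leukocyte markers (median 0.34; adjusted p = 0.799 with an estimated correlation), while endothelial markers had a median of -0.0088; Schwann cell markers (-0.25, but 0.13 without knockout 2) decide nothing. A smaller share of RNA from muscle fibres would raise these alike, but the fibroblast mean minus the endothelial mean, in log2 CPM, was 0.41 (SE 0.13) higher in knockouts, with 0.917 to 1.17 in each knockout and 0.463 to 0.820 in each control. Tendon or fascia taken with the muscle may contribute: 6 tendon genes outside the list (Scx, Mkx, Comp, Thbs4, Chad and Kera) had a median of 0.43, close to the list's 0.42, with camera p of 0.0217 at the preset and 0.259 at an estimated correlation, and ranged from -0.22 for Scx to 0.70 for Kera. Fibroblasts of the muscle itself also express some of these genes. A change of the fibroblasts with genotype stays open as well.

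The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 5 genes higher, and the highest count in a direction among the others was 3, so 1 split reached 5; 2 splits reached the 3 genes lower, again with 3 as the highest other. For the gene lists 6 of the 10 splits gave at least the 8 of the real split, and the highest other gave 14. That split set controls 1 and 2 and knockout 1 against the rest, and it called 0 genes by edgeR, with 483 at an unadjusted p under 0.05 and no other tool run on it. At an unadjusted p under 0.05 the real split had 1640 genes and the split of controls 1 and 2 and knockout 3 against the rest 1830, so the real split was not the largest by this count. With an estimated correlation the real split gave 0 lists and the others at most 1. For the other splits this check was added after these counts were seen. The preset of 0.01 lay far below the correlation estimated in some lists, such as 0.782 for slow-twitch genes and 0.592 for fibroblast markers. It lay above the estimates for thermogenesis (-0.0228), FoxO targets (-0.0111) and lipid synthesis (0.00223). Those lists lost their calls as well, so a higher correlation does not account for every lost call. For thermogenesis the camera p went from 2.99e-06 at the preset to 0.00710 at its lower estimated correlation. The settings therefore differ in more than the correlation, and a lost call does not by itself show correlated members.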
